A study of Mus musculus with 2 samples.

How the data were processed

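The samples were 2 libraries of small RNA below 30 nt from mouse forebrain at embryonic day 15.5, per the labels biological replicates 1 and 2, made from separate pools of embryos. Whether the pools shared a litter, dissection day or library batch is not given in the sources used here, so the spread between them may be partly technical. Each file held whole-number counts of reads per miRNA gene as deposited by the authors, with no normalization. Per the deposited README text the counts were made from alignments to the mm10 genome with GENCODE M4 annotation. The aligner, the counter and their settings are not given in the sources used here. The files had no header and 4 columns: the gene identifier, counts on either strand and counts on each strand. The first count column equalled the sum of the other 2 in every gene row.

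The strand column with the larger total was taken as the strand of the RNA, by a rule fixed before the data were examined, since no source named it. The fixed design, gene groups and alternative settings were, unless stated, written before the data were examined. The 4 rows that name no gene were kept out of library sizes and tests. Of all reads, 44.6% in replicate 1 and 42.4% in replicate 2 were in the multi-mapping row, 14.3% and 18.2% in the unmapped row, 3.03% and 3.07% in the row for no feature and 0 in the ambiguous row. Reads placed at more than 1 locus thus stayed outside the gene rows, and levels of genes with near-identical copies are uncertain. Counts are per gene and do not tell the arms of a precursor apart.

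Gene symbols, coordinates and hosts came from GENCODE M21, on the same genome build, by gene identifier. Of 1973 gene rows, 1894 matched and 79 did not. All coordinates are of mm10, counted from 1. An exon or intron of a host is as that later annotation gives it, over any transcript of the host. Sequences of the miRNA precursors came from the transcripts of the same annotation, and no genome sequence was used.

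CPM was the count divided by the sum over gene rows, scaled so that each library sums to 1000000. A gene was detected with at least 10 counts in each library. Means and SDs are over n = 2 libraries, and log2 levels had 1 CPM added. The difference between the libraries was tested for each gene with at least 10 counts in total by a two-sided exact binomial test of the counts given their sum, against the libraries' shares of gene counts, with Benjamini-Hochberg adjustment at 0.05. Ratios are log2 of replicate 2 over replicate 1, with 0.5 counts added to each library. Depth limits and intervals used 3 counts as the floor and 95% Clopper-Pearson intervals. The spread between replicates was the square root of edgeR's common dispersion with TMM factors and an intercept-only design. No quasi-likelihood test was run, since no contrast exists within 1 group.

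The level of a gene group was the median of its matched genes, with its percentile among 10000 random lists of the same size. The library difference of a group was the median log2 ratio of its detected genes, with its percentile among 10000 random lists in which each gene was replaced by one of the 50 genes nearest in mean expression. Clusters were detected genes on 1 strand with neighbours within 10 kb, and the permutation test used 100000 resamples. Clopper-Pearson intervals were computed for strand shares.

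The 20 fixed groups were neuron-enriched, neural progenitor, Mir17-92 and paralogs, let-7, miR-125 and miR-99/100, Dlk1-Dio3, other imprinted loci, glial, Hox-cluster, erythroid, immune cell, endothelial, mesenchyme and mural cell, muscle, liver, gut and pancreas, epithelial and olfactory, sensory organ, choroid plexus and pigment epithelium, pluripotent stem cell and Drosha-independent miRNAs. The rule for named genes took the 20 genes with the highest mean CPM, up to 3 matched genes of highest mean CPM in each group, and the 10 called genes with the largest absolute log2 ratio and a mean of at least 10 CPM. It also took the highest and lowest member of the 3 clusters with the most detected genes, and the 3 genes with the highest opposite-strand share among those with at least 100 counts over both strands in each library, ties broken by gene identifier. Other genes named were chosen after their values were seen: Mirlet7a-2 and Mirlet7b in the report, and those said to be so in the closing section. A list of choroid plexus and ciliated cell miRNAs was also made after the data were seen, and is used only in the closing section.

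The alternatives were TMM and DESeq2 scaling, a total without the most abundant gene, the column for either strand, other count minimums, pseudocounts of 0.5 and 10 CPM, other cluster distances, other backgrounds for random lists and leaving out each replicate. The test between libraries was tried on simulated data in which 200 genes were changed. Over the 458 genes that passed the count minimum, it recovered 55.7% of the 97 genes changed by 0.5 on the log2 scale and 79.6% of the 98 changed by 1, and called 3 of 263 unchanged genes. With at least 100 counts in total it recovered 89.8% and 100% of these. The simulated counts held counting error only, and the test was given the true shares of the libraries. These rates therefore do not cover errors of scaling or spread between replicates. A simulated coefficient of variation of 0.1 was recovered as 0.0998. R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.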

Results

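Small RNAs below 30 nt were sequenced from the forebrain of mouse embryos at day 15.5, the part of the embryonic brain that gives rise to the cortex, striatum, thalamus and hypothalamus. The design held 1 group with 2 biological replicates of the B6NCrl strain, each a pool of male and female embryos. Replicate 1 pooled the tissue of 78 embryos and replicate 2 that of 62 embryos. MicroRNAs (miRNAs) are short RNAs, cut from hairpin precursors, that lower the output of the messenger RNAs they pair with. The libraries answer which miRNA genes were represented in this tissue, at what level, and how far the pools differed. With 1 group, no comparison between conditions was possible, and every test below compares these 2 libraries or sets of genes within them.

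Replicate 1 held 11743597 reads, of which 4464927 were counted on the strand of a miRNA gene (38.0%, Clopper-Pearson 95% interval 38.0 to 38.0). Replicate 2 held 13074292 reads, of which 4753555 were counted in this way (36.4%, interval 36.3 to 36.4). Levels are given as normalised counts (CPM, which sum to 1000000 over the miRNA genes of a library), as mean ± SD with n = 2 libraries unless stated. A gene with no count in a library had an upper limit of 0.672 CPM in replicate 1 and 0.631 CPM in replicate 2, the level of 3 counts. Reads without molecular identifiers are not independent molecules, so intervals, floors and tests on counts cover counting error only.

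Among reads counted in gene rows, the forebrain profile was dominated by Mir99a, at 296792 ± 20567 CPM, 4.95 times the next gene. Reads placed at more than 1 locus, 44.6% of all reads in replicate 1 and 42.4% in replicate 2, had no part in this ranking. Ranks and shares over all miRNAs of the tissue may therefore differ. Mir99a (chromosome 16, 77598936 to 77599000) lies in an intron of its noncoding host gene Mir99ahg and held 28.2% of the counts in replicate 1 and 31.1% in replicate 2. Mirlet7g followed at 59954 ± 7963 CPM, in an intron of Wdr82 (chromosome 9, 106178840 to 106178927), then Mir100 at 38471 ± 906 CPM, in an intron of the noncoding gene 3110039I08Rik (chromosome 9, 41531425 to 41531504). Mirlet7i (37334 ± 1629 CPM), Mir335 (37289 ± 4085 CPM), in an intron of the imprinted gene Mest, and Mir17 (33935 ± 596 CPM), in an exon of Mir17hg, came next. The order of Mir100, Mirlet7i and Mir335 was not separated, since their means differed by less than the SD of Mir335. Mir17 was not separated from Mir335 by the same measure, although Mir335 was higher in both libraries. Mir335 stood at 40178 CPM against 34356 CPM for Mir17 in replicate 1, and at 34401 CPM against 33514 CPM in replicate 2. The order of close ranks further down was not tested.

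Further down the profile stood Mir130a (24922 ± 527 CPM), Mir99b (21918 ± 1284 CPM), Mir30e (20640 ± 1764 CPM) and Mir149 (19413 ± 108 CPM). They were followed by Mir93 (18609 ± 627 CPM), Mir126a (16117 ± 369 CPM), Mir487b (14700 ± 1472 CPM), Mir26b (14170 ± 2322 CPM) and Mir181c (14083 ± 278 CPM). Mir322 (13346 ± 258 CPM), Mir20a (12929 ± 928 CPM), Mir30a (10980 ± 647 CPM), Mirlet7d (9335 ± 1063 CPM) and Mir106b (9249 ± 9.59 CPM) closed the 20 most abundant genes. The top 10 genes held 59.1% and the top 20 held 72.4% of the counts in gene rows, and rank 1 exceeded rank 20 by 32.1-fold. Of 1973 miRNA gene rows, 724 had a count in either library and 370 were detected, with at least 10 counts in each. With a minimum of 1 count in each library, 592 rows were detected.

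**Figure D1:**
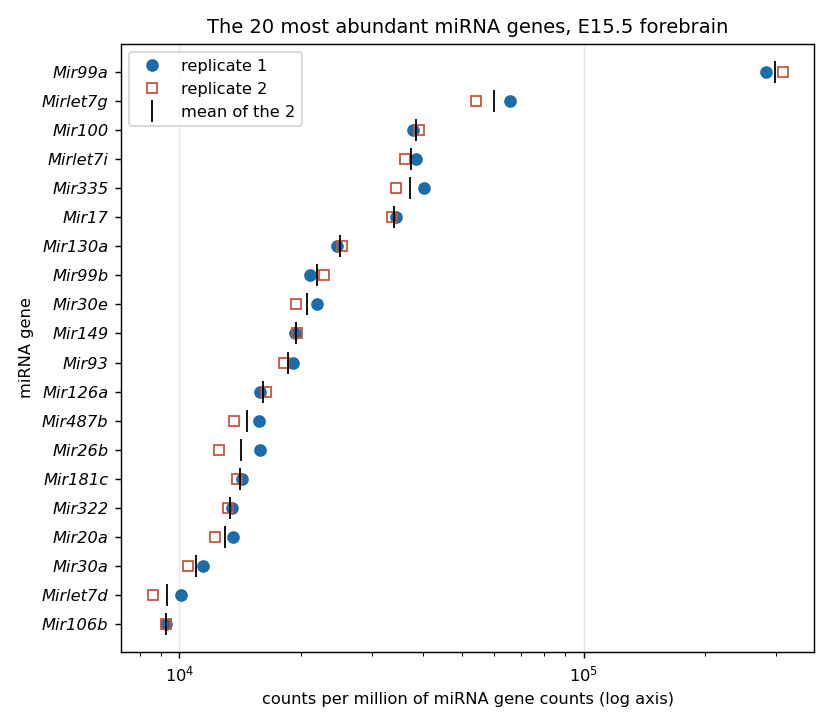
Normalised counts (CPM, log axis) for the 20 most abundant miRNA genes, with filled circles for replicate 1, open squares for replicate 2 and a bar for their mean. Mir99a stands 4.95 times above Mirlet7g, and the largest gap between the libraries is that of Mir26b, with a log2 ratio of -0.34.

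Among the gene groups fixed before the data were examined, the group of miR-125 and miR-99/100 genes was the most abundant. Genes of these families sit beside let-7 genes in several clusters. The 6 genes of the group summed to 36.7% of the counts, and Mir99a alone held 29.7% of the counts. Mir100 and Mir99b came next, and the group ran from 1936 to 296792 CPM. The let-7 family, which accumulates as embryonic tissues differentiate, held 12.7% over 10 matched genes, from 224 CPM for Mirlet7a-2 to 59954 CPM for Mirlet7g. Mirlet7e and Mirlet7f-1 had no row, and 5 of the 10 genes share sequence with other miRNA genes, so this share may be too low. The Mir17-92 cluster and its paralogs, which are linked to proliferation, held 8.25% over 15 genes, led by Mir17, Mir93 and Mir20a. The imprinted Dlk1-Dio3 cluster on chromosome 12, expressed from the maternal chromosome, had all 42 of its matched genes detected and held 5.11%, led by Mir487b, Mir369 (6416 ± 463 CPM) and Mir127 (5387 ± 162 CPM). Of its 48 listed genes, 6 had no row, so this share may also be too low. Other imprinted loci held 4.22% over 5 genes, most of it from Mir335, with Mir296 at 3004 ± 379 CPM and Mir298 at 1878 ± 147 CPM.

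The neuron-enriched miRNAs held 2.04% of the counts over 15 genes. Mir137 was the highest at 9092 ± 926 CPM, followed by Mir139 (3862 ± 15.0 CPM) and Mir153 (2112 ± 427 CPM), the last in an intron of Ptprn2. The Mir124a genes of this group stood at 2.80, 2.25 and 1.05 CPM. They share sequence, and reads placed at more than 1 locus were not counted. Their true rank and the share of the group are therefore uncertain. The neural progenitor group held 0.628% over 3 matched genes, with Mir92b at 5547 ± 814 CPM, Mir9-3 at 733 ± 21.2 CPM and Mir9-2 at 3.26 ± 0.451 CPM. Mir9-2 and Mir9-3 share sequence with each other and with Mir9-1, so their levels are uncertain where reads fell on more than 1 copy. The glial group, whose Mir219a and Mir338 rise with oligodendrocyte differentiation, stayed at 0.0441%, with Mir219a-1 at 215 ± 24.1 CPM, Mir338 at 205 ± 5.35 CPM and Mir219a-2 at 21.2 ± 0.477 CPM.

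Markers of other cell types were also measured. Endothelial Mir126a, in an exon of Egfl7, held 1.61%. The mesenchyme and mural cell group held 0.643% over 8 genes, led by Mir143 (3459 ± 219 CPM) and Mir140 (2772 ± 300 CPM), with Mir214 at 92.9 ± 17.4 CPM. The Drosha-independent group, whose precursors bypass the nuclear cutting step, held 0.335%, led by Mir484 (2781 ± 144 CPM), Mir320 (439 ± 11.6 CPM) and Mir877 (73.0 ± 10.1 CPM). The epithelial and olfactory group held 0.182%, with Mir203 at 1181 ± 110 CPM, Mir429 at 391 ± 17.5 CPM and Mir200b at 87.8 ± 1.28 CPM. The choroid plexus and pigment epithelium pair held 0.149%, with Mir204 at 1480 ± 483 CPM and Mir211 at 5.27 ± 2.99 CPM.

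The remaining groups were low by reads counted in gene rows. The liver, gut and pancreas group held 0.0542%, led by Mir375 (273 ± 76.8 CPM), with Mir192 at 84.9 ± 1.30 CPM and the liver miRNA Mir122 at 77.1 ± 16.2 CPM. The Hox-cluster group, which marks posterior body levels, held 0.0381%, with Mir10a at 218 ± 37.5 CPM, Mir10b at 127 ± 25.2 CPM and Mir196b at 27.2 ± 2.33 CPM. The sensory organ group held 0.0272% through Mir182 (138 ± 45.5 CPM), Mir183 (102 ± 22.2 CPM) and Mir96 (31.2 ± 9.97 CPM). The pluripotent stem cell clusters held 0.0269%, nearly all from Mir302a (106 ± 1.61 CPM), Mir302d (90.9 ± 1.26 CPM) and Mir302b (58.9 ± 0.922 CPM). The immune cell group held 0.0241%, with Mir223 at 88.0 ± 15.1 CPM, Mir155 at 77.3 ± 12.9 CPM and Mir146 at 37.7 ± 1.71 CPM. This leaves out Mir142, which had no row of its own: opposite-strand counts at its position, in the row of Mir142b, stood at 188 ± 0.361 CPM, above any counted member of the group. The erythroid group held 0.0152%, with Mir451a at 92.0 ± 10.04 CPM, Mir144 at 44.4 ± 7.70 CPM and Mir486 at 15.8 ± 0.219 CPM. The muscle group held 0.00633%, with Mir208b at 38.0 ± 4.61 CPM, Mir206 at 12.7 ± 11.1 CPM and Mir208a at 6.81 ± 1.08 CPM. Its Mir1a-1, Mir133a-1 and Mir133a-2 rows had no counts, and whether their reads were lost as multi-mapping was not tested.

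Against 10000 random lists of the same size from all rows, 18 of the 20 groups had a median level at or above the upper end of the central 95% of those lists. The exceptions were the erythroid group (percentile 96.1) and the choroid plexus and pigment epithelium pair (percentile 95.8). Most rows had no counts, and against random lists of detected genes only 3 groups stood as high: let-7 (percentile 99.9), miR-125 and miR-99/100 (percentile 99.99) and Dlk1-Dio3 (percentile 98.1). All matched genes of these 3 groups were detected, while undetected members draw some other groups, such as the muscle and pluripotent ones, lower against detected genes by construction. These percentiles describe these libraries, and genes are not replicates.

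**Figure D2:**
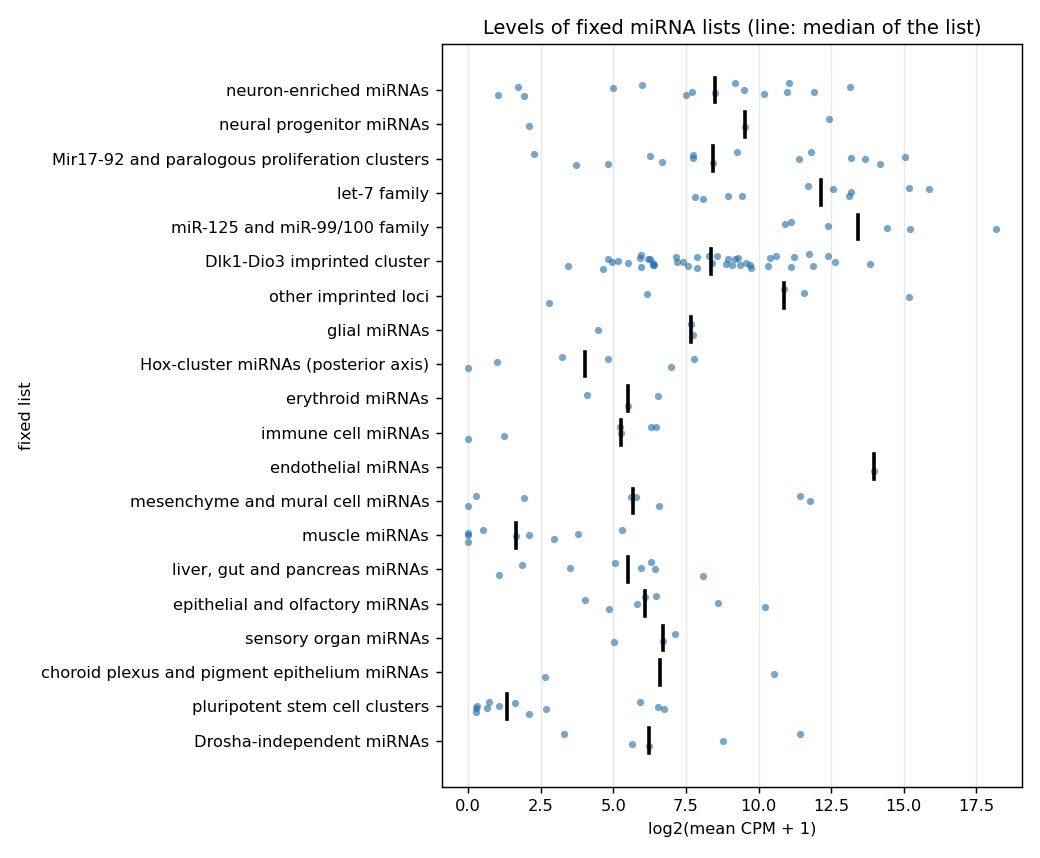
Levels of the 20 fixed miRNA groups as log2(mean CPM + 1), with a point per matched gene (spread vertically at random) and a line at the median of each group. By the mean over libraries of log2(CPM + 1), which differs slightly from the plotted value at low levels, the let-7 median was 12.13. By the same measure it was 13.40 for miR-125 and miR-99/100, against 1.31 for the pluripotent and 1.57 for the muscle group.

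Neighbouring miRNA genes often differed widely in level. The largest cluster, 30 detected genes on chromosome 12 (109709060 to 109747960) in the Dlk1-Dio3 region, ran from Mir487b at 14700 ± 1472 CPM to Mir544 at 9.89 ± 3.86 CPM, a 1486-fold range. The next, 10 genes upstream (109563692 to 109594599), ran from Mir127 down to Mir493 at 27.4 ± 1.39 CPM, a 196-fold range. The Mir17-92 cluster on chromosome 14 (115043671 to 115044506) ran from Mir17 to Mir19b-1, at 12.2 ± 3.60 CPM, a 2787-fold range over 6 genes within 1 host transcript, though Mir19b-1 shares sequence with Mir19b-2. Over 43 clusters of 150 detected genes, the mean SD within a cluster was 2.59 on the log2 scale, against 2.82 with cluster labels shuffled (two-sided permutation test across genes, p = 0.285). With neighbours within 50 kb the permutation p was 0.0496, so the outcome depended on how a cluster was defined. In 15 of the 43 clusters, some genes share sequence with another annotated miRNA gene and others do not. The sharing genes were lower in 14 of the 15, with a mean log2 difference of -3.79, a comparison chosen after values were seen. Reads placed at more than 1 locus were not counted, which may have widened the spread within clusters. The test therefore cannot decide whether neighbours lacked a common level.

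The libraries were close for most genes. Of the 370 detected genes, 307 (83.0%) lay within a log2 ratio of 0.5 either way, and the median absolute log2 ratio was 0.19. Across genes, which are not independent replicates, Pearson's r of log2 CPM was 0.994 and Spearman's rho was 0.993. The spread between replicates, as the edgeR coefficient of variation, was 15.0%, falling from 17.4% at a log2 CPM of 4 to 13.1% at 13. The libraries were counted as 2 samples because the labels give them as separate pools. Their counts were not those of 1 library deposited again (chi-square 38252.7 on 456 degrees of freedom), which does not show by itself that the pools differed.

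Of 457 genes tested, 166 differed between the libraries beyond counting error, 88 higher and 78 lower in replicate 2 (exact binomial test, Benjamini-Hochberg adjusted p below 0.05). The share called higher was 53.0%, against 42.9% with TMM scaling and 69.1% with Mir99a left out of the total, so the split between directions depended on scaling. Of the called genes, 14 had an absolute log2 ratio of at least 1, of which 9 were higher and 5 lower in replicate 2. With a minimum of 100 counts in total, 4 genes were called at that size. The test compares 2 libraries, not conditions, and no called difference here has a replicate check.

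The named differences were led by Mir206, a skeletal muscle miRNA, with 92 counts in replicate 1 and 23 in replicate 2 (log2 ratio -2.07, exact binomial test, adjusted p = 2.53e-11). Mir200a (chromosome 4, 156054896 to 156054985) was higher in replicate 2, with a log2 ratio of 1.47 (exact binomial test, adjusted p = 1.09e-25). Mir193b was higher by 1.33, and Mir129-1, Mir1247, Mir129-2 and Mir1249 were higher by 0.99, 0.99, 0.98 and 0.94 on the log2 scale. Mir129-1 and Mir129-2 share part of their sequence, so their levels are uncertain where reads fell on both. Mir34c was lower in replicate 2 with a log2 ratio of -1.02, and Mir1264 and Mir1298, both in introns of the serotonin receptor gene Htr2c on chromosome X, were lower with log2 ratios of -0.99 and -0.96. Adjusted p-values of these 10 genes by the exact binomial test were at most 7.88e-06, for Mir193b.

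Among the 20 most abundant genes, 18 were called, 5 higher and 13 lower in replicate 2, against 2 higher and 15 lower with TMM scaling and 10 higher and 9 lower with Mir99a left out of the total. The largest of their ratios was -0.34, for Mir26b. Mir17, Mir181c and Mir322 were called lower with log2 ratios of -0.036, -0.040 and -0.039, and were higher with Mir99a left out of the total. Mir149 (0.011) and Mir106b (0.0021) were not called, but both were called lower with TMM scaling and higher with Mir99a left out of the total. With TMM scaling Mir100, Mir130a and Mir126a were not called, and with Mir99a left out Mir93 was not.

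In 6 of the 20 groups the median library difference lay outside the central 95% of random lists matched on expression, and in 4 when genes needed at least 100 counts in each library. Random lists drew each gene on its own, while the 3 sensory organ genes lie in 1 cluster on chromosome 6 and the Dlk1-Dio3 genes in 1 region. Genes of 1 locus may move together, so percentiles of such groups may overstate how unusual the groups were. In let-7, 9 of 10 genes were lower in replicate 2 and Mirlet7b was not called (it was lower with TMM and DESeq2 scaling and higher with Mir99a left out of the total), with a group median of -0.24 (percentile 0.07), and the median stayed below 0 under every scaling run. In the miR-125 and miR-99/100 group 5 genes were higher and 1 lower, with a median of 0.13 (percentile 98.1). The median stayed above 0 under every scaling run, but with TMM scaling 4 genes were higher and Mir100 lost its call. The Dlk1-Dio3 group had 18 genes lower, 5 higher and 19 not called, with a median of -0.05 (percentile 0.49), which became 0.0095, with 12 genes lower and 6 higher, when Mir99a was left out of the total. All 3 sensory organ genes were lower, with a median of -0.66 (percentile 0.51) and Mir182 at -0.68. Both choroid plexus and pigment epithelium genes were lower, Mir204 at -0.68 and Mir211 at -1.20 (percentile 0.15), but with at least 100 counts in each library Mir204 alone was left and lay inside the range (percentile 6.39). The liver, gut and pancreas group had 3 genes lower and 1 higher (2 lower and 1 higher with Mir99a left out of the total), with a median of -0.19 (percentile 0.96), which became 0.031 (percentile 27.1, inside the range) over its genes with at least 100 counts in each library. The same numbers of genes as these were called when p was adjusted over the list alone in each of the 6 groups.

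The other 14 groups lay inside that range. The Hox-cluster group had 3 genes higher and 1 not called (median 0.38), and the mesenchyme and mural cell group 3 higher and 3 not called (median 0.19). The neuron-enriched group had 5 higher, 2 lower and 8 not called (median 0.05), against 4 higher and 5 lower with TMM scaling and 7 higher and 1 lower with Mir99a left out of the total, so it had no direction that held across scalings. In that group 8 genes passed when adjusted over the list alone. The Mir17-92 group had 4 higher, 3 lower and 8 not called (median 0.09), against 10 higher and 1 lower with Mir99a left out of the total. The epithelial and olfactory group had 2 higher and 5 not called (median -0.03), the Drosha-independent group 2 higher and 3 not called (median 0.11), and other imprinted loci 2 higher, 2 lower and 1 not called (median 0.16, and -0.032 with at least 100 counts in each library). With TMM scaling Mir429 of the epithelial group was called lower and Mir877 of the Drosha-independent group was not called. The immune group had Mir223 higher, Mir155 lower and 3 genes not called (median 0.18). The erythroid group had Mir144 higher and 2 genes not called (median 0.22), and Mir144 was not called with TMM or DESeq2 scaling, while 2 genes passed when adjusted over the list alone. Endothelial Mir126a was higher by 0.05 and was not called with TMM scaling. The neural progenitor group had Mir92b higher and 2 genes not called (median -0.06), and Mir9-3 was called lower with TMM and DESeq2 scaling. The glial group had Mir219a-1 higher and 2 not called (median 0.05), and the muscle group Mir206 lower and 4 not called (median 0.28). No gene of the pluripotent group was called among 7 tested (median 0.03). The medians of the neural progenitor and epithelial groups turned above 0 with Mir99a left out of the total, and that of the pluripotent group turned below 0 with TMM scaling. In the 12 groups other than the neuron-enriched and erythroid ones, the counts adjusted over the list alone were the same.

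**Figure D3:**
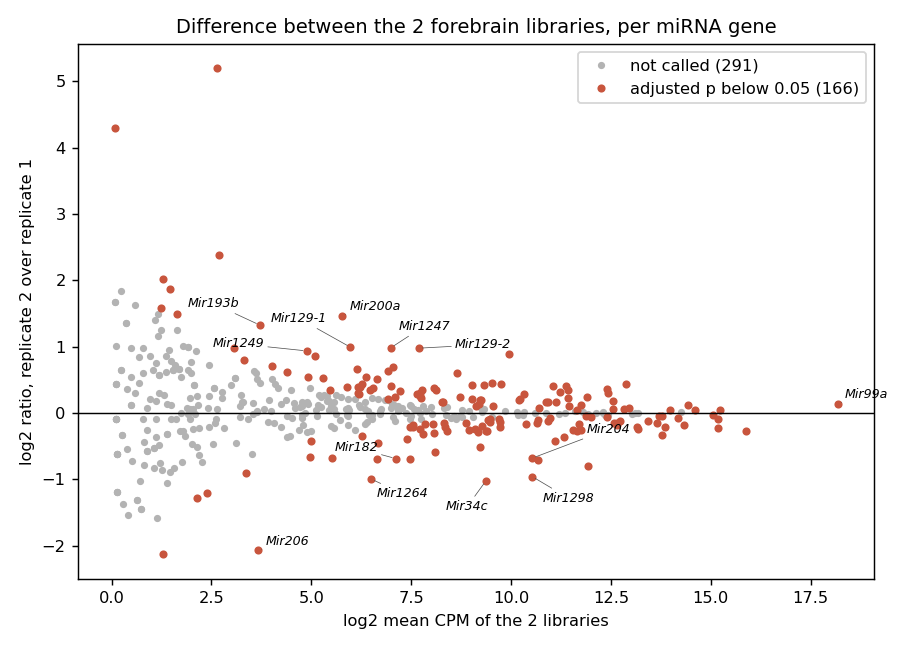
Log2 ratio of CPM, replicate 2 over replicate 1, against log2 mean CPM for the 457 tested miRNA genes, with red points for the 166 genes called different and grey points for the rest. Mir206 lies lowest of the labelled genes at -2.07 and Mir200a highest at 1.47, and Mir99a lies at the right at 0.14.

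Reads on the strand opposite to a row's gene made up 1.59% of counts over both strands in replicate 1 (Clopper-Pearson 95% interval 1.577 to 1.600) and 1.49% in replicate 2 (interval 1.475 to 1.496). They were concentrated in 11 rows, which held 143202 of 143736 such counts (99.6%). In the rows of Mir142b (chromosome 11, 87756841 to 87756955), Gm25927 (chromosome 17, 17830343 to 17830459) and Gm24083 (chromosome 9, 108568295 to 108568414), all counts lay on the opposite strand. The annotation places Mir142, Mirlet7e and Mir191 on the other strand at these positions, without rows of their own in the counts. If the opposite-strand counts are reads of such genes, the let-7, immune, neural progenitor and Dlk1-Dio3 groups lacked members counted in this way. Antisense transcripts at these positions were not told apart from the annotated genes.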

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

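The tests on opposite-strand counts in this part were chosen after the counts had been seen. Multi-mapping reads are given because they exceed the depth of the gene counts themselves, and the opposite-strand rows because their counts lie far above the 3 counts that a count of 0 allows.

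Outside the gene counts, 5240531 reads of replicate 1 and 5543873 reads of replicate 2 were placed at more than 1 locus, 117% of the gene counts in each library. They were not assigned to any gene.

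Opposite-strand counts summed over both libraries were 36892 in the row of Gm25927, 30092 in Gm24321, 24544 in Gm24083, 23903 in Gm25252, 11176 in Gm25301 and 4850 in Gm25750. Mir497b held 4519, Mir299b 3930, Mir142b 1736, Gm24111 959 and Gm25641 601. The rows overlap Mirlet7e, Mir409, Mir191, Mir376a, Mir378a, Mir380, Mir497, Mir299a, Mir142, Mirlet7f-1 and Mir9-1, in that order, on the other strand. As levels of the opposite strand, Gm25927 stood at 4005 ± 152 CPM and Gm24321 at 3273 ± 389 CPM (SD, n = 2).

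A candidate explanation is that these are reads of miRNA genes on the other strand that had no row of their own. Of all opposite-strand counts, 99.7% lay in rows that overlap such a gene in the later annotation. A general loss of strand information in the libraries was argued against, since rows with at least 1000 counts over both strands in each library had a median opposite-strand share of 0%. No biological explanation was tested, and antisense transcripts at these positions were not told apart from the annotated genes.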

How the results depend on the processing

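Alternatives were planned, except those said to be added after seeing the data. Calls within 1.5 times the main count held for the 166 genes that differed, which numbered from 156 to 181, with 147 to 164 of the main calls shared where scaling, strand column or a minimum of 100 counts changed. Of named genes, 430 of 458 alternative log2 ratios and 404 of 480 alternative levels were the same. The cause was not tested for the changes below, unless stated. At least 1 count in each library gave 592 detected genes, by construction. The share of the top 20 genes was 71.3% with the column for either strand, 62.1% with the most abundant gene left out of the total, and 72.45% to 72.46% leaving out a replicate. With at least 100 counts in total, 4 called genes had an absolute log2 ratio of at least 1. With DESeq2 the coefficient of variation, the square root of the median gene dispersion, was 0.0495, against 0.150 with edgeR. The DESeq2 value is from a median of gene estimates, not a common value. Against detected genes, 3 group levels stood at or above the upper end of the central 95% of random lists. The mean SD within clusters lay below shuffled by -0.42 for neighbours within 50 kb (permutation p = 0.0496) and by -1.76 over all annotated miRNA genes (permutation p = 2e-05, the smallest they can give), most of which had no counts. The opposite-strand share was 2.17% with the most abundant gene left out.

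With at least 100 counts in each library, 4 group differences and not 6 lay outside the central 95% of random lists: the choroid plexus and pigment epithelium pair, left with Mir204 at -0.68, moved to percentile 6.39 and the liver, gut and pancreas group to percentile 27.1, since fewer genes entered. In that setting the medians of groups inside the range also turned, to -0.032 for other imprinted loci, 0.12 for neural progenitor, 0.080 for epithelial and -0.028 for pluripotent miRNAs. Reversed values, past the test on at least 1 side, were the liver, gut and pancreas difference, at 0.031 in that setting, and log2 ratios with the most abundant gene left out of the total of 0.024 for Mir17, 0.019 for Mir181c, 0.020 for Mir322 and 0.052 for Mir139. With TMM, Mir149 was at -0.029 and Mir106b at -0.038, and with DESeq2 size factors Mir106b was at -0.025. These scalings shift every ratio by a constant, -0.040 for TMM, -0.027 for DESeq2 and 0.060 with the most abundant gene left out. Added after seeing the data, that last scaling turned the Dlk1-Dio3 median to 0.0095.

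No paired analysis was possible because there is 1 group. Leaving out a replicate left 1 library and no value for differences or spread. The planned comparison of single-copy and multi-copy genes needs a genome and was not run. Below 100 counts, depth limits the calls.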

Other observations

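Tests in this part on shared sequence within let-7 and between cluster neighbours, and on counting error in choroid plexus miRNAs, were chosen after the values had been seen, as was the use of the adjusted p to judge the let-7 test. The genes named here outside the fixed rule were also chosen after their values were seen.

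Among the epithelial miRNAs, Mir200a stood at 28.9 CPM in replicate 1 and 80.2 CPM in replicate 2, while its neighbours Mir200b and Mir429, also in introns of Ttll10, had log2 ratios of -0.03 and -0.09 and were not called, although Mir429 was called lower with TMM and DESeq2 scaling. Mir7b, a neuroendocrine miRNA, fell from 2036 CPM in replicate 1 to 1249 CPM in replicate 2, a log2 ratio of -0.71. Mir101a moved the other way, from 693 to 1290 CPM, a log2 ratio of 0.90. The Mir302 genes of pluripotent cells, Mir302a, Mir302d and Mir302b, stood at 106, 90.9 and 58.9 CPM with SDs of at most 1.61, while their cluster mates Mir302c and Mir367 stood at 5.41 ± 0.681 and 0.210 ± 0.298 CPM, and Mir293 of the Mir290 cluster at 3.23 ± 1.08 CPM. The 3 Mir124a genes, which give the main neuronal miRNA, stood at 2.80, 2.25 and 1.05 CPM, uncertain because they share sequence.

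MiRNAs of the choroid plexus and of multiciliated cells were lower in replicate 2. Of 11 detected genes, all had ratios below 0, 8 were called lower and 0 higher, with a median log2 ratio of -0.83, among them Mir449a (3882 ± 1475 CPM), Mir34c, Mir448, Mir204, Mir1264 and Mir1298. The genes are not independent: Mir449a, Mir449b and Mir449c lie in 1 cluster, Mir34b and Mir34c in another, and Mir448, Mir1264, Mir1298 and Mir1912 in Htr2c. Ratios also differed between cluster mates, with Mir34b at -0.25 and Mir449c at -0.14. For the 8 called genes, counting error was argued against by their calls, which were adjusted over all tested genes. Since the list was chosen after most of its ratios had been seen, the number of calls gives no support to it as a set. GC content of the precursor was argued against by a median of -0.85 after a linear fit on GC. A candidate explanation is a larger share of choroid plexus tissue in the pool of replicate 1, which stayed open: Mir1912, the one detected list gene whose ratio had not been looked at, had a log2 ratio of -0.83 on 17 and 10 counts, too few to decide it. The sensory organ genes Mir96, Mir182 and Mir183 were also lower in replicate 2, with a median of -0.66, so the change was not particular to this list, which was made from these data and shares Mir204 and Mir211 with a fixed group.

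Genes that share a 22 nt stretch with another annotated miRNA gene may have low levels because reads placed at more than 1 locus were left out. Of 5 comparisons, let-7 genes had medians of 497 CPM with such a stretch and 9335 CPM without (5 against 5, exact permutation test, p = 0.0476, adjusted p = 0.119). Detected genes of the fixed groups gave p = 0.554 and all detected genes p = 0.587 and, at 18 nt, p = 0.564 (permutation tests). Each of these had the higher median for genes with a shared stretch. The comparisons of detected genes left out genes with counts below the minimum for detection. They therefore cannot decide whether lost reads lowered genes with a shared stretch, since the genes lowered most may have been left out. The fifth, added after those 4 and after low members of some clusters had been seen, set neighbours in 15 clusters against each other and gave a mean log2 difference of -3.79, lower in 14 clusters (permutation p = 0.000300, adjusted p = 0.00150), and without the Mir99a cluster -3.40 (permutation p = 0.000500). In the 7 clusters outside let-7 that had not prompted the test, a subset set apart after all values were seen, the difference was -2.45, lower in 6, with a permutation p of 0.146, so the effect was not shown apart from the clusters that prompted the test. The mean difference of -3.79 therefore does not separate lost reads from low transcription or processing of these genes, and neither could be excluded.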
